A study of Mus musculus with 3 samples.

How the data were processed

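The samples were B220+ cells of the spleen and Venus+ CD138hi cells of the spleen and of the bone marrow, sorted by flow cytometry from IL-10 Venus reporter mice, with 1 array for each. Per the series' design text and the labels, total RNA was purified, amplified and labelled with Cy5, fragmented and hybridized to a mouse oligonucleotide array of Toray's 3D-Gene platform, which was read with the maker's scanner and extraction software. Per the file headers, the deposited scanner files hold the median intensity of each spot in the Cy5 channel and a local background, and the spot median was used here. Versions of the extraction software and the number of mice per sort are not given in the sources used here.

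The authors deposited a second table of processed intensity values. Per the series' design text, the authors subtracted from each spot the mean of the blank spots within a 95% interval and set the median of the detected signals to 25. Set against the scanner values, this table is linear, uncentred and rounded to 0.1, and each array runs in the direction of its spot medians, so scale, centring and direction are known. The blank level that gave these values was the mean of the middle 90% of the 2736 blank spots of an array (2462 spots), with that mean plus 2 SD as the detection limit. Computed that way from the scanner files, detection calls differed from the table for 0 probes on each array. Among table values of 10 or more, the largest relative difference was 0.976% in B220+, 4.05% in spleen Venus+ and 2.89% in bone marrow Venus+ cells. The median of each column of the table was 25.

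All values given here were computed from the scanner files by this recipe. The detection limit lay at a spot median of 46.2 in B220+, 42.7 in spleen Venus+ and 43.7 in bone marrow Venus+ cells, against a median spot of 60.5, 54.6 and 51.2. The lowest detected normalized signals were 1.34, 1.74 and 2.35. Spots marked as faulty by the scanner (0, 1 and 2) were left out, and saturated spots (0, 1 and 1) were kept. Control, blank and empty spots entered no gene value. A normalized signal is set against the same probe on another array, never against another probe.

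Gene names came from the platform annotation supplied for the probes. Of 23473 probes, 16631 had 1 gene symbol, 0 had several and 6842 had none and are unnamed here. With the RefSeq gene table of GRCm38.p6, used for names alone, 12622 symbols were current, 3947 were updated through a synonym held by a single gene, 59 had a synonym shared by several genes and 3 were not found, and the last 2 kinds kept the symbol given. For a gene with several probes, the probe with the highest mean log2 signal over the 3 arrays stood for the gene. Probes of a gene differed. Among genes with 2 detected probes, the median difference between their log2 ratios was 0.68 over 128 genes for spleen Venus+ against B220+, 1.08 over 104 genes for bone marrow Venus+ against B220+ and 0.63 over 108 genes for bone marrow against spleen Venus+.

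A gene counted as higher or lower when it was detected on both arrays and its normalized signals differed at least 2-fold. A gene with a probe detected on 1 array of a comparison and none on the other was counted apart. Its fold is a lower bound, the bright array's signal over the higher of the lowest detected signal of the dim array and the signal of the dim probe itself. No test was made and no p-value is given, because each population has 1 array. The spot error of a log2 ratio combines, for both arrays, the SD of the blank spots (0.670, 0.868 and 1.18 in normalized signal for B220+, spleen Venus+ and bone marrow Venus+ cells) with the relative SD of the positive control spots, 24 copies of each (7.57%, 5.77% and 5.21%).

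The 31 fixed gene lists were the plasma cell programme, mature B cell identity, MHC class II presentation, ER protein folding and unfolded protein response, secretory pathway and translocon, cytokines, transcription factors linked to Il10, cell cycle, chemokine receptors and adhesion, B cell receptor signalling, Toll-like receptor signalling, surface markers of regulatory B and plasma cells, class-switch recombination and its DNA repair, apoptosis regulators, amino acid transport and mTOR signalling, oxidative phosphorylation, glycolysis, cytosolic ribosomal proteins, type I interferon response, immediate-early genes and immunoglobulin genes. To these came markers of immature B cells, T cells, NK cells, monocytes and macrophages, neutrophils and granulocyte precursors, dendritic and plasmacytoid dendritic cells, erythroid cells, megakaryocytes and platelets, basophils, mast cells and eosinophils, and stromal and endothelial cells. For each list with at least 5 members detected on both arrays, the median log2 ratio was set against 10000 random lists of the same size matched on mean log2 signal in 20 bins, as a description of these arrays. "Above 34 of 10000 random lists" means that 34 random medians were lower. Some genes are in more than 1 list.

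The genes named for each comparison followed a rule. They were Il10, Prdm1, Sdc1, Ptprc, Irf4, Xbp1, Pax5, Bach2, Bcl6 and Ighm, and some further genes of the rule are not reported here. To these came the 5 largest and 5 smallest log2 ratios among genes with a signal of at least 25 on either array, leaving out immunoglobulin genes and clone or prediction names. The rule also took up to 2 largest and 2 smallest members of each list described, any detected cytokine or immunoglobulin gene, and the 3 largest bounds in each direction. Groups, comparisons, thresholds, lists, the naming rule and all alternatives but the detection limit from spots without a probe were fixed before the data were examined.

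The alternatives were scaling to the probes detected on all 3 arrays, quantile normalization and cyclic loess over those probes, normexp background correction with an offset of 50, a limit at the 25th percentile of detected signals, no filter with undetected signals set to the lowest detected one, the mean over a gene's probes, the deposited value table, and a 4-fold threshold. A detection limit from the mean plus 2 SD of spots without a probe was added after the data were seen. An alternative log2 ratio or list median within 1.5-fold of the reported one, and a count within 1.5 times, was taken as unmoved. Because the comparisons with B220+ cells share an array, their overlap is given beside that of independent lists and beside 100 simulated draws of unchanged arrays.

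The calculations were tested on simulated arrays with 200 genes changed by known folds and the measured spot errors of each array. The signals of the B220+ array, with undetected ones at 0, stood for all 3 arrays, so the Venus+ signals did not enter. All 50 genes raised 4-fold, 50 raised 3-fold, 50 lowered 3-fold and 50 lowered 4-fold were called in each comparison, which ran on 11548, 11261 and 11133 genes for spleen Venus+ against B220+, bone marrow Venus+ against B220+ and bone marrow against spleen Venus+. Genes raised 4-fold had median log2 ratios of 1.88, 1.79 and 1.88 in that order, and genes lowered 4-fold -2.05, -2.20 and -2.08. Ratios in the simulation thus came out shifted downward, with no such shift planted. In the same order, 0 of 5923, 0 of 5769 and 0 of 5765 unchanged genes with signals of at least 25 were called, and 66 of 5425 (1.22%), 69 of 5292 (1.30%) and 70 of 5168 (1.35%) dimmer ones. A planted list of 20 genes stood at percentile 100 in each comparison, and 4, 1 and 3 of 100 random lists fell outside the middle 95%. The simulation holds no spread between sorts or mice, and none from amplification, labelling or the probes. Its shares of unchanged genes called thus cover spot error alone and may be too low for the real arrays. On those, the ratios of 2 detected probes of a gene lay within 2-fold for 60.2%, 49.0% and 75% of such genes, in the same order. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.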

Results

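Gene expression was measured in B cells and plasma cells sorted from IL-10 Venus reporter mice, in which the fluorescent protein Venus marks cells that express Il10. The 3 populations were B220+ cells of the spleen, Venus+ CD138hi cells of the spleen and Venus+ CD138hi cells of the bone marrow. B220, an isoform of CD45, is a surface marker of B cells, and CD138 (syndecan-1) is a surface marker of plasma cells. RNA of each population was hybridized to 1 single-colour oligonucleotide array, so there were 3 arrays and no replicates. Of the 23473 probes on the array, 16917 (72.1%) were detected in B220+ cells, 17239 (73.4%) in spleen Venus+ cells and 15857 (67.6%) in bone marrow Venus+ cells. The probes with a gene symbol stood for 16390 genes, of which 12165, 12422 and 11525 were detected on the 3 arrays in the same order. A total of 10769 genes were detected on all 3 arrays and 3292 on none.

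With 1 array per population, no difference given here has a replicate check and none was tested. Array and population cannot be told apart. The error given with a log2 ratio is a spot error, which covers the spread of spots within the arrays and not the spread between mice or sorts, and the number of arrays limits the precision of every value. Genes detected on both arrays of a comparison are called higher or lower when their normalized signals differed at least 2-fold. For a gene detected on 1 of the 2 arrays, the fold is a lower bound, written as "at least".

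The first comparison set Venus+ CD138hi cells against B220+ cells of the same organ, the spleen. The series deals with IL-10 made by IgM+ CD138hi cells under the control of Blimp1, so the genes of IL-10, Blimp1 and IgM are given first. Il10 was 14.9-fold higher in the Venus+ cells (log2 ratio 3.90 ± 0.21, spot error), with normalized signals of 88.8 and 5.94. Since these cells were sorted on Venus, which marks Il10 expression, a higher Il10 follows from the gate and is no separate finding. Prdm1, which encodes Blimp1, a repressor that drives plasma cell differentiation, was 9.35-fold higher (log2 ratio 3.22 ± 0.18). The probe of Ighm, the IgM heavy chain gene, was 222-fold higher (log2 ratio 7.79 ± 0.16), with a signal of 2433 against 11 in B220+ cells. Pax5 and Bach2, transcription factors of the mature B cell, were 7.73-fold and 13.6-fold lower (log2 ratios -2.95 ± 0.15 and -3.76 ± 0.15). With the normexp background, an alternative that shrinks the ratios of dim genes, Il10 stood at 1.61 and Prdm1 at 1.41. Bcl6, a transcription factor of germinal centre B cells, was detected in B220+ cells and not in spleen Venus+ cells, at least 7.15-fold lower.

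Sdc1 and Ptprc are the genes of CD138 and CD45, of which B220 is an isoform. The labels give no gate on B220 or CD45 for the Venus+ cells, and Ptprc is not the gene of B220 alone, so its ratio is no check of a gate. Sdc1, which encodes CD138, was 51.3-fold higher in the spleen Venus+ cells (log2 ratio 5.68 ± 0.41), and Ptprc, which encodes CD45, was 4.94-fold lower (log2 ratio -2.31 ± 0.14). Irf4 and Xbp1, transcription factors of plasma cells, were 3.52-fold and 20.2-fold higher. Of the immunoglobulin genes, 3 had a named probe. Besides Ighm, IglV1 was 5.45-fold higher (log2 ratio 2.45 ± 0.14), and Ighe, the IgE heavy chain gene, was detected on neither spleen array. The part of the Ighm transcript that its probe reads is not given in the sources used here, so membrane and secreted forms were not separated and the folds given for Ighm hold for this probe alone.

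**Figure D1:**
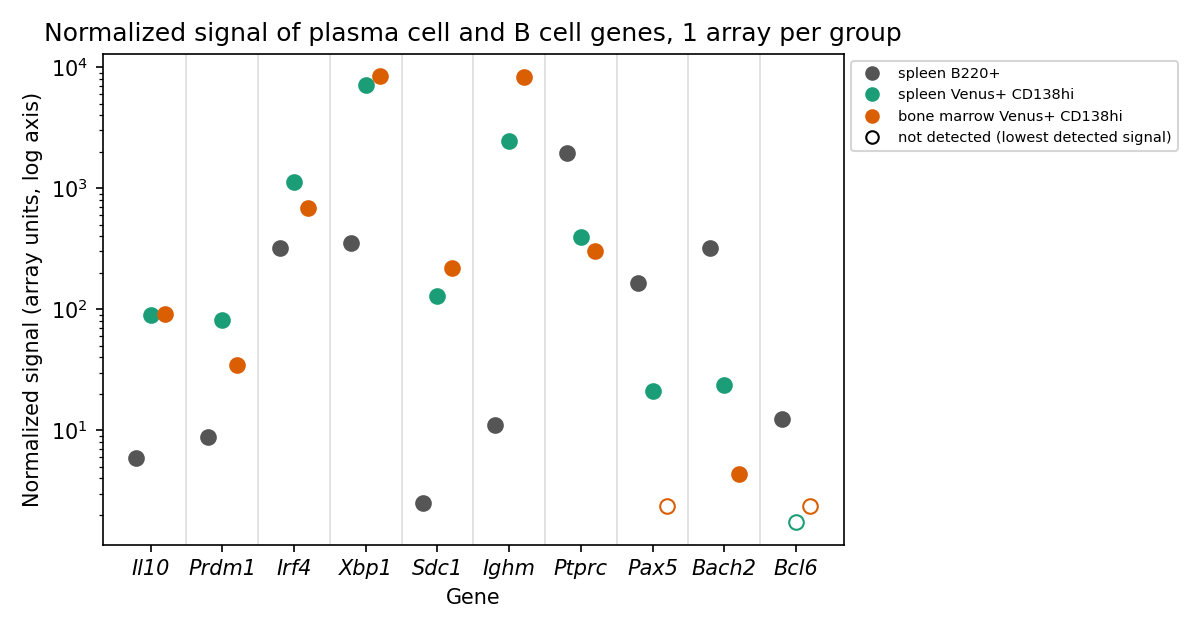
Normalized signal in array units, on a log axis, of 10 genes on the 3 arrays, with 1 point per array in spleen B220+, spleen Venus+ CD138hi and bone marrow Venus+ CD138hi cells. Open circles mark genes not detected, drawn at the lowest detected signal of the array; Il10 stood at 5.94, 88.8 and 91.3 in the same order, and Bach2 at 323, 23.8 and 4.37.

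Across the spleen, 11618 genes were detected in both populations. Of these, 1828 were at least 2-fold higher in Venus+ cells and 1915 at least 2-fold lower, and the median log2 ratio of all genes was -0.02. The difference exceeded 2 spot errors for 3673 of these 3743 genes. The 2-fold threshold alone passes that limit for all but dim genes, so this count lends the calls no support. A further 803 genes were detected in Venus+ cells alone, 513 of them with a bound of at least 2-fold, and 547 in B220+ cells alone, 149 of them with such a bound. The largest log2 ratios were those of Prg2 (10.24), Chst1 (8.30), Tent5c (8.03), Pla1a (7.81) and Tmem176a (7.62). The smallest were those of S100a8 (-7.04), Ccr6 (-6.59), Cpm (-6.41), Cnn3 (-6.20) and Ngp (-6.00). Tnfrsf17, which encodes the plasma cell survival receptor BCMA, was at least 1068-fold higher, Tfpi2 at least 239-fold and Oosp2 at least 116-fold. S100a9 was at least 1469-fold lower, Camp at least 282-fold and Tmem108 at least 98.4-fold. With a normexp background in place of the subtraction of blank spots, 410 genes were higher and 1174 lower, which took the higher share of these genes from 48.8% to 25.9%. With a detection limit taken from spots without a probe, 2219 were higher and 1047 lower, a higher share of 67.9%.

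Many genes that make and export antibody were higher in the spleen Venus+ cells. In the plasma cell programme, 21 of 25 genes detected in both populations were higher, 0 were lower and 4 lay between, with a median log2 ratio of 3.17, above all 10000 random lists matched on signal. Prg2 and Chst1 had its largest ratios, and Tnfrsf13b (-0.40 ± 0.14) and Bhlha15 (-0.10 ± 0.14) its smallest. Of 32 genes of ER protein folding and the unfolded protein response, 23 were higher and 1 lower, with a median of 1.66, also above all 10000 random lists. Sel1l, an adaptor of ER-associated degradation, stood at 4.80 ± 0.17, and Eif2ak3, which encodes the stress sensor PERK, at -1.04 ± 0.14. In the secretory pathway and translocon, 22 of 47 genes were higher and 0 lower, with a median of 0.88, above all 10000 random lists. Tram2 (3.11 ± 0.28) and Sec62 (2.86 ± 0.14) led this list, and Copb1 (-0.58 ± 0.14) and Srp9 (-0.42 ± 0.14) closed it.

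Many genes of the mature B cell were lower in the spleen Venus+ cells. Of 29 genes of mature B cell identity, 19 were lower, 0 higher and 10 between, with a median log2 ratio of -1.39, below all 10000 random lists. Id3 (-4.15 ± 0.14) and Bach2 lay lowest, and Blk (0.45 ± 0.14) and Pkig (0.25 ± 0.14) highest. In B cell receptor signalling, 11 of 24 genes were lower and 0 higher, with a median of -0.94, above 34 of 10000 random lists. The adaptor gene Bank1 stood at -3.35 ± 0.14 and the inhibitory co-receptor gene Cd22 at -2.81 ± 0.14. MHC class II presentation had 8 measured genes, 3 lower, 1 higher and 4 between, with a median of -0.86, above 542 of 10000 random lists. Ciita, the master regulator of class II genes, stood at -1.86 ± 0.14, Ifi30 at -2.59 ± 0.14 and Rfx5 at 2.16 ± 0.18. The cell cycle list had 19 of 37 genes lower, 2 higher and 16 between, with a median of -1.22, below all 10000 random lists; it was -0.60 with the normexp background and -0.61 with the limit from spots without a probe, both under 2-fold. The kinetochore genes Cenpe (-3.77 ± 0.71) and Bub1 (-2.68 ± 0.65) were lowest, with signals of 1.81 and 1.97 in the Venus+ cells, and E2f1 (1.05 ± 0.19) and Tk1 (1.01 ± 0.14) highest.

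Cytokine genes went both ways. Of 26 detected in both spleen populations, 10 were higher and 8 lower, with a median of 0.29, above 8268 of 10000 random lists. Il13 (5.0 ± 0.14), Il10, Il23a (3.83 ± 0.31) and Ebi3 (2.98 ± 0.14), which encodes a subunit of IL-27 and IL-35, were highest. Il12a (-3.66 ± 0.20) and Tnf (-2.77 ± 0.54) were lowest. Among transcription factors linked to Il10, 7 of 25 were higher and 6 lower, with a median of 0.06, above 7407 of 10000 random lists. That median turned negative under 3 of 9 other settings. Fos (7.60 ± 0.18) and Jun (4.23 ± 0.14) led this list, and Rora (-2.53 ± 0.17) and Crtc2 (-1.61 ± 0.15) closed it. Immediate-early genes, which respond within minutes to activation and to cell handling, had 9 of 20 members higher and 1 lower, with a median of 0.81, above all 10000 random lists. In that list Dusp2 stood at -2.09 ± 0.14.

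Among chemokine receptors and adhesion genes, 6 of 24 were higher and 9 lower in the spleen Venus+ cells, with a median of -0.66, above 226 of 10000 random lists. Cxcr3 (3.42 ± 0.71) and Ccr9 (3.27 ± 0.27) were highest, and Ccr6 and Gpr183 (-3.97 ± 0.14), which guide B cells within lymphoid organs, lowest. Of 27 genes of class-switch recombination and its DNA repair, 4 were lower, 0 higher and 23 between, with a median of -0.56, above 439 of 10000 random lists. Exo1 stood at -1.41 ± 0.39, Msh6 at -1.22 ± 0.14 and Batf at 0.74 ± 0.14. Surface markers of regulatory B and plasma cells had 9 of 24 genes higher and 2 lower, with a median of 0.27. It stood above 9049 of 10000 random lists and turned negative under 1 of 9 other settings. The inhibitory receptor gene Ctla4 (5.41 ± 0.51) and Cd5 (4.72 ± 0.34) were highest, and Cd40 (-2.37 ± 0.14) lowest.

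Markers of other cell types also differed between the spleen populations. Neutrophil and granulocyte precursor markers had 6 of 9 genes lower in Venus+ cells and 2 higher, with a median of -2.79, below all 10000 random lists, and 6 more were detected in B220+ cells alone. With those at their bounds the median over 15 genes was -3.66. T cell markers had 10 of 15 genes higher and 0 lower, with a median of 1.76, above all 10000 random lists, and Cd247 at 5.35 ± 0.15. Markers of basophils, mast cells and eosinophils had 5 of 6 higher and 0 lower, with a median of 1.5, and this list holds Prg2, a gene of the plasma cell list too. Of stromal and endothelial markers, 4 of 7 were higher and 0 lower, with a median of 1.02. It stood above 9545 of 10000 random lists, within their middle 95%. With the normexp background the medians were 0.49 for T cell, 0.64 for basophil, mast cell and eosinophil and 0.26 for stromal and endothelial markers, -1.51 for granulocyte markers and 2.04 for the plasma cell programme. The median was 0.06 for 9 monocyte and macrophage markers, which turned negative under 1 of 9 other settings, with Cd68 at 1.75 ± 0.14 and Fcgr3 at -2.46 ± 0.55. Another 7 of these markers were detected in B220+ cells alone and 1 in Venus+ cells alone, and with bounds the median over 14 genes was -0.37. The median was -1.37 for 6 erythroid markers, led downward by Car2 (-4.85 ± 0.65) and Tfrc (-3.21 ± 0.15), and turned positive under 2 of 8 other settings.

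The normexp background took 48 of 108 named genes of this comparison from at least 2-fold to under it. Among them were Cxcr3 (0.61), Tnf (-0.35), Cenpe (-0.61), Bub1 (-0.23), Tram2 (0.92), Rfx5 (0.82), Exo1 (-0.07), Msh6, Crtc2, E2f1, Tk1, Cd68 and Fcgr3 (-0.24). The remaining settings did so for 17, among them Eif2ak3 (-0.69 with the limit from spots without a probe).

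**Figure D2:**
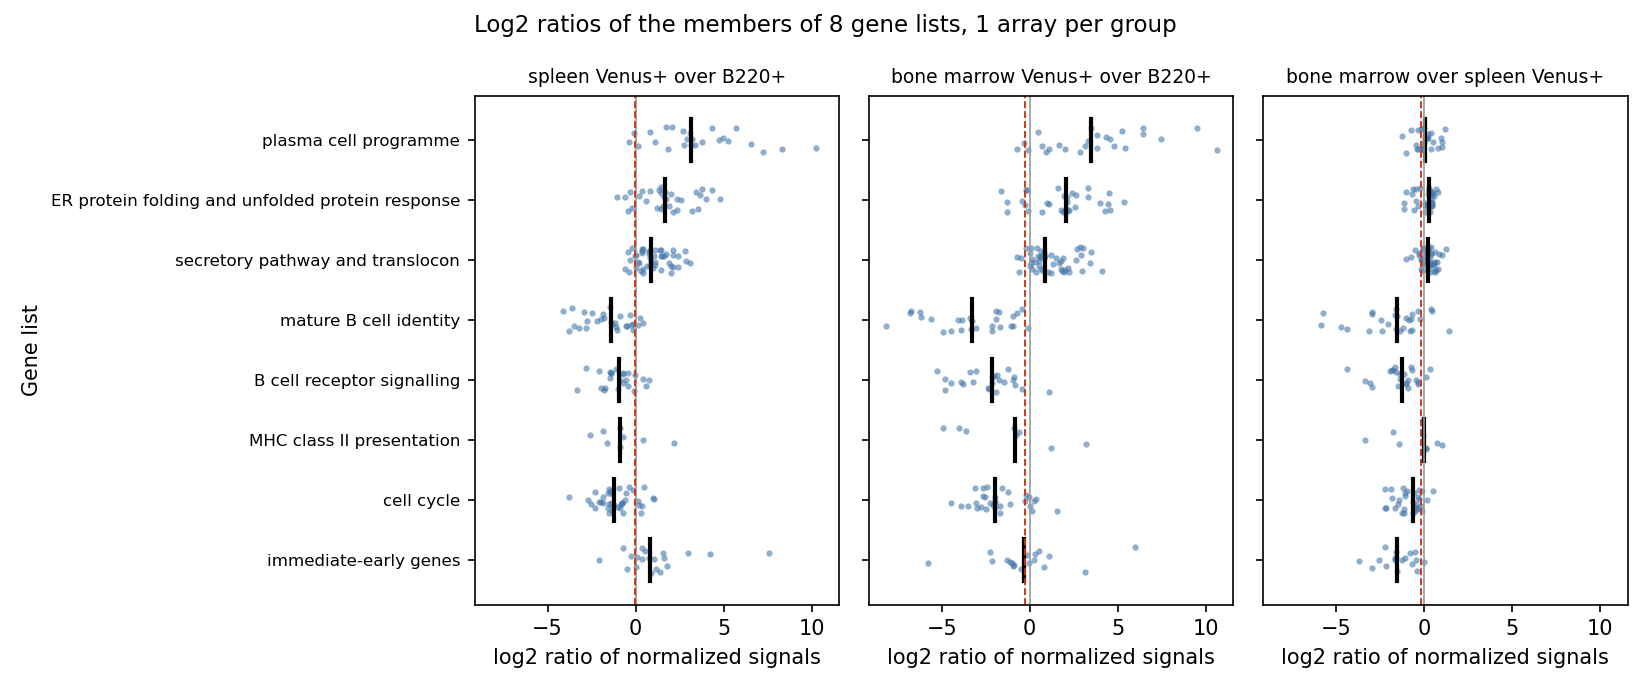
Log2 ratios of normalized signals (x axis, 1 point per gene detected on both arrays) for the members of 8 gene lists (y axis) in the 3 comparisons, 1 array per population. Black bars are list medians, the red dashed line is the median of all genes and the grey line is 0; the plasma cell programme had medians of 3.17, 3.46 and 0.06 from left to right, the last turning negative under 2 of 9 other settings, and mature B cell identity -1.39, -3.28 and -1.55.

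The second comparison set bone marrow Venus+ CD138hi cells against spleen B220+ cells, so organ and cell type differed together. Il10 was 15.4-fold higher in the bone marrow Venus+ cells (log2 ratio 3.94 ± 0.21), again a difference that follows from the Venus gate. Ighm was 751-fold higher (9.55 ± 0.16), Xbp1 23.7-fold (4.57 ± 0.13) and Sdc1 88.0-fold (6.46 ± 0.41). Prdm1 was 3.95-fold higher (1.98 ± 0.18) and Irf4 2.14-fold (1.10 ± 0.13), and with the normexp background these ratios were 0.69 and 0.58, under 2-fold, and that of Il10 was 1.55. Bach2 was 74.1-fold lower (-6.21 ± 0.41) and Ptprc 6.54-fold lower (-2.71 ± 0.13). Pax5 and Bcl6 were detected in B220+ cells and not in bone marrow Venus+ cells, at least 69.9-fold and 5.28-fold lower. IglV1 was 4.65-fold higher (2.22 ± 0.13), and Ighe, with a signal of 73.3, was detected in bone marrow Venus+ cells alone, at least 54.5-fold higher.

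A total of 10813 genes were detected in both bone marrow Venus+ and B220+ cells. Of these, 2424 were at least 2-fold higher and 3320 at least 2-fold lower. The difference exceeded 2 spot errors for 5644 of 5744, again largely through the 2-fold threshold itself. The median log2 ratio of all genes was -0.24, and it was 0.05 when the arrays were scaled to the probes detected on all 3. That scaling gave 3056 higher and 2609 lower genes, a higher share of 53.9% in place of 42.2%. The medians of gene lists in this comparison are therefore given relative to the median of all genes. Counts of higher and lower genes in the lists are not adjusted in this way and depend on the scaling. They stand beside 22.4% higher and 30.7% lower among all genes. Another 711 genes were detected in bone marrow Venus+ cells alone, 653 with a bound of at least 2-fold, and 1350 in B220+ cells alone, 561 with such a bound. With the normexp background 578 genes were higher and 2142 lower. The largest log2 ratios were those of Prg2 (10.63), Chst1 (9.49), Tmem176a (9.43), Stard9 (8.89) and Pla1a (8.69). The smallest were those of Cnn3 (-8.38), Bcl11a (-8.19), Ccr6 (-7.66), Btg1 (-7.39) and Cd72 (-6.81). Tnfrsf17 was at least 2185-fold higher, Shh at least 511-fold and Tfpi2 at least 442-fold. Samd9l was at least 684-fold lower, Ms4a4c at least 385-fold and S1pr1, a receptor for egress from lymphoid organs, at least 372-fold.

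In the plasma cell programme, 19 of 25 genes were higher in bone marrow Venus+ than in B220+ cells, 0 lower and 6 between, and the list median lay 3.71 above the median of all genes. Tnfrsf13b (-0.73 ± 0.13) and Glcci1 (-0.32 ± 0.13) had its smallest ratios. ER protein folding and the unfolded protein response had 22 of 32 genes higher and 3 lower and lay 2.28 above all genes, with Sel1l at 5.36 ± 0.16, Xbp1 at 4.57 and Eif2ak3 at -1.63 ± 0.13. The secretory pathway and translocon had 23 of 47 genes higher and 0 lower and lay 1.09 above all genes, with Sec62 at 4.10 ± 0.13 and Ssr4, a translocon-associated subunit, at 3.48 ± 0.13. Each of these 3 medians stood above all 10000 random lists.

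Mature B cell identity had 22 of 27 genes lower in bone marrow Venus+ cells, 0 higher and 5 between, with a median at -3.04 relative to all genes. Bcl11a and Cd72 lay lowest and Fcrla (-0.08 ± 0.13) and Pkig (-0.46 ± 0.13) highest. B cell receptor signalling had 19 of 24 lower and 1 higher, at -1.88 relative to all genes, with the kinase gene Prkcb at -5.30 ± 0.18, Bank1 at -4.84 ± 0.14 and Cd81 at 1.08 ± 0.13. The cell cycle list had 23 of 31 genes lower and 1 higher, at -1.71 relative to all genes, with Cenpa at -4.45 ± 0.15, the replicative helicase gene Mcm4 at -3.92 ± 0.15 and E2f1 at 1.57 ± 0.19. These 3 medians stood below all 10000 random lists. MHC class II presentation had 3 of 8 genes lower and 2 higher, at -0.59 relative to all genes and above 2098 of 10000 random lists. Its members H2-Aa (-4.95 ± 0.13) and Ifi30 (-4.03 ± 0.13) were lowest, and Rfx5 (3.18 ± 0.17) and Ctss (1.20 ± 0.13) highest.

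Of 24 cytokine genes detected in both, 11 were higher in bone marrow Venus+ cells and 5 lower, at 0.79 relative to all genes and above 9465 of 10000 random lists. Il23a (5.45 ± 0.30), Il13 (4.89 ± 0.14), Il10 and Ebi3 (3.44 ± 0.13) were highest and Il12a (-5.09 ± 0.52) lowest. Transcription factors linked to Il10 had 6 of 22 higher and 9 lower, at -0.69 relative to all genes and above 588 of 10000 random lists, with Fos at 6.0 ± 0.18, Jun at 3.16 ± 0.13, Sp1 at -3.19 ± 0.43 and Nfkb1 at -2.83 ± 0.14. Immediate-early genes had 3 of 18 higher and 5 lower, at -0.09 relative to all genes and above 5275 of 10000 random lists, with Dusp2 at -5.76 ± 0.25. Chemokine receptors and adhesion genes had 6 of 22 higher and 10 lower, at -0.67 relative to all genes and above 845 of 10000 random lists, with the integrin gene Itgal at 3.04 ± 0.16 and the follicle-homing receptor gene Cxcr5 at -6.74 ± 0.26. Class-switch recombination and its DNA repair had 19 of 26 lower and 1 higher, at -0.90 relative to all genes and above 309 of 10000 random lists. In that list the DNA damage kinase gene Atm stood at -3.38 ± 0.23, Id2 at -2.79 ± 0.43 and the polymerase gene Polh at 1.27 ± 0.16. Surface markers of regulatory B and plasma cells had 10 of 23 higher and 7 lower, at 0.36 relative to all genes. Their median stood above 7569 of 10000 random lists. In that list the granzyme gene Gzmb stood at 4.36 ± 0.14, Ctla4 at 3.69 ± 0.52 and Cd86 at -4.36 ± 0.41. The unadjusted median of that list turned negative under 1 of 9 other settings.

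Among markers of other cell types, neutrophil and granulocyte precursor genes had 9 of 14 lower in bone marrow Venus+ than in B220+ cells and 4 higher, at -2.83 relative to all genes, below all 10000 random lists. S100a9 (-5.20 ± 0.13) and Chil3 (-4.77 ± 0.31) were lowest, and Mpo (3.75 ± 0.46) and Ly6g (3.10 ± 0.13) highest. T cell markers had 8 of 11 higher and 1 lower, at 1.85 relative to all genes, with Cd247 at 6.05 ± 0.15, Cd8b1 at 3.24 ± 0.22 and Cd2 at -5.51 ± 0.24, and 3 more were detected in bone marrow and 4 in B220+ cells alone. Markers of basophils, mast cells and eosinophils (4 of 6 higher, 0 lower, Prg2 among them) lay 2.46 above all genes, and stromal and endothelial markers (3 of 5 higher, 0 lower) lay 2.08 above. Erythroid markers (0 of 7 higher, 3 lower) lay at 0.25 and monocyte and macrophage markers (3 of 10 higher, 4 lower) at 0.07 relative to all genes, and their unadjusted medians changed sign under 4 and 5 of 9 other settings. With the normexp background the unadjusted medians were 2.38 for the plasma cell programme (3.46 as reported), -0.87 for cell cycle (-1.96), 0.50 for T cell (1.61), 0.70 for basophil and related (2.22), 0.50 for stromal (1.83) and -1.78 for granulocyte markers (-3.07). For mature B cell identity it was -2.51 (-3.28), for ER folding 1.35 (2.03), for Il10-linked factors -0.31 (-0.93) and for chemokine receptors -0.17 (-0.92), and cyclic loess gave -0.25 for Il10-linked factors. The normexp background took 40 of 113 named genes from at least 2-fold to under it, among them Ctla4 (0.82), Mpo (0.89), Sp1 (-0.78), Id2 (-0.56), Polh (0.49), Cd81, Ctss and E2f1, and the remaining settings did so for 7.

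The comparisons against B220+ cells share that array. Among 10769 genes detected on all 3 arrays, 1587 were higher in both Venus+ populations, out of 1790 in spleen and 2414 in bone marrow, and 1551 were lower in both, out of 1613 and 3313. Independent lists of these sizes would share 401 and 496 genes. Unchanged arrays set against the shared control shared 295 and 296 genes in 100 simulated draws with a log2 SD of 0.52 per array, a spread that also holds any biological difference between the Venus+ arrays. Part of the overlap may come from the shared array. In opposite directions went 7 genes that were higher in spleen and lower in bone marrow Venus+ cells, and 1 that was lower and higher. With the normexp background 344 genes were higher in both, with probes above the 25th percentile 850, and with the limit from spots without a probe 762 were lower in both. Fos, Jun and Sel1l were among the genes higher in both populations, and Ccr6, Bach2 and Cnn3 among those lower in both.

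The third comparison set the same sort, Venus+ CD138hi, in bone marrow against spleen. Il10 differed by less than its spot error between the organs, with signals of 91.3 and 88.8 (log2 ratio 0.04 ± 0.11), and its ratio turned negative under 2 of 9 other settings. Both sorts were gated on the same Il10 reporter, so similar levels may follow from the gate. Ighm was 3.38-fold higher in bone marrow (1.76 ± 0.11), and Ighe was detected in bone marrow alone, at least 42.2-fold higher. Prdm1 was 2.37-fold lower in bone marrow (-1.24 ± 0.12), between -0.99 and -0.72 under the other 3 scalings and the normexp background, short of 2-fold. Bach2 was 5.46-fold lower (-2.45 ± 0.41), with -0.44 under the normexp background, and Pax5 was detected in spleen alone, at least 9.04-fold lower. Sdc1 stood at 0.78 ± 0.11 and reached 1.14 under cyclic loess. Irf4 (-0.71 ± 0.11), Ptprc (-0.40 ± 0.11), Xbp1 (0.23 ± 0.11) and IglV1 (-0.23 ± 0.11) differed less than 2-fold, and Bcl6 was detected in neither.

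Of 11352 genes detected in both Venus+ populations, 492 were at least 2-fold higher in bone marrow and 1720 at least 2-fold lower. The difference exceeded 2 spot errors for 2139 of 2212, again largely through the 2-fold threshold itself. The split between the directions depends on the scaling. The median of all genes was -0.17, and scaled to the probes detected on all arrays it was 0.16, with 1250 higher and 916 lower genes, a higher share of 57.7% in place of 22.2%. Quantile normalization gave 916 higher and 1162 lower genes (44.1%), cyclic loess 670 and 1069 (38.5%), and the normexp background 62 and 315. List medians are again given relative to all genes. Counts of higher and lower genes in the lists are again not adjusted, and stand beside 4.33% higher and 15.2% lower among all genes. Another 173 genes were detected in bone marrow alone, 74 with a bound of at least 2-fold, and 1068 in spleen alone, 306 with such a bound. The largest log2 ratios were those of Dlgap1 (3.70), Prodh2 (3.63), Ccdc60 (3.34), Nanos3 (3.32) and Rnase2b (3.26), of which Ccdc60 (0.85) and Rnase2b (0.73) were under 2-fold with the normexp background. The smallest were those of Cxcr5 (-5.84), Cd72 (-5.73), Ly86 (-5.72), Cd2 (-5.08) and Btg1 (-4.87). S100a9 was at least 40.0-fold higher in bone marrow, Mpo at least 17.1-fold and Camp at least 12.1-fold. Adm was at least 265-fold lower, S1pr1 at least 82.3-fold and Samd9l at least 61.5-fold.

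Many B cell genes were lower in the bone marrow than in the spleen Venus+ cells. Mature B cell identity had 17 of 27 genes lower and 1 higher, at -1.38 relative to all genes, with Cxcr5 and Cd72 lowest and Fcer2a (1.41 ± 0.11) highest. B cell receptor signalling had 15 of 24 lower and 0 higher, at -1.07, with Blk at -4.35 ± 0.12, Prkcb at -3.33 ± 0.16 and Cd81 at 0.34 ± 0.11. Transcription factors linked to Il10 had 13 of 22 lower and 0 higher, at -1.0, with the aryl hydrocarbon receptor gene Ahr at -3.86 ± 0.26 and Egr2 at -2.57 ± 0.26. Immediate-early genes had 12 of 18 lower and 0 higher, at -1.37, with Dusp2 at -3.66 ± 0.24 and Egr1 at -2.93 ± 0.12. Each of these 4 medians stood below all 10000 random lists. Unadjusted, the normexp background took mature B cell identity from -1.55 to -0.93, Il10-linked factors from -1.17 to -0.41 and immediate-early genes from -1.54 to -0.82, each under 2-fold. The unadjusted median of B cell receptor signalling was -1.25 and came as near to 0 as -0.78 among the other settings, also under 2-fold. Class-switch recombination and its DNA repair had 9 of 26 lower and 0 higher, at -0.59 and above 36 of 10000 random lists, with Id2 at -3.08 ± 0.42, Atm at -2.59 ± 0.22 and Polh at 0.69 ± 0.14. The cell cycle list had 14 of 31 lower and 0 higher, at -0.45 and above 116 of 10000 random lists, with Mcm3 at -2.19 ± 0.23 and Hmmr at -2.18 ± 0.32. Surface markers of regulatory B and plasma cells had 8 of 23 lower and 0 higher, at -0.44 and above 132 of 10000 random lists, with Cd5 at -3.43 ± 0.25, Cd86 at -3.37 ± 0.41 and Gzmb at 0.93 ± 0.11.

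Most genes of antibody production lay within 2-fold between the organs. In the plasma cell programme 3 of 26 genes were higher in bone marrow, 2 lower and 21 between, at 0.23 relative to all genes. Chst1 (1.20 ± 0.11) and Ly6c1 (1.05 ± 0.11) were highest and Prdm1 and Zbtb20 (-1.03 ± 0.11) lowest. ER protein folding and the unfolded protein response had 0 of 33 higher and 2 lower, at 0.46 and above 9939 of 10000 random lists, and the secretory pathway and translocon had 2 of 48 higher and 1 lower, at 0.40 and above 9954 of 10000. Ero1a, an ER oxidase gene, stood at -1.11 ± 0.20 and Sec62 at 1.24 ± 0.11. Cytokine genes had 2 of 24 higher and 4 lower, at 0.21, with Il23a at 1.62 ± 0.12 and Il16 at -1.49 ± 0.12. MHC class II presentation had 1 of 8 higher and 3 lower, at 0.20, with H2-Aa at -3.33 ± 0.11 and Rfx5 at 1.02 ± 0.12. The unadjusted medians of the plasma cell, cytokine and MHC class II lists changed sign under 2, 1 and 2 of 9 other settings. Among chemokine receptors and adhesion genes 1 of 23 was higher and 10 lower, at -0.41 and above 267 of 10000 random lists. Ccr10, a receptor of mucosal plasma cells, stood at 2.66 ± 0.14 and Pecam1 at -3.14 ± 0.46.

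Neutrophil and granulocyte precursor markers had 5 of 9 genes higher in bone marrow than in spleen Venus+ cells and 0 lower, at 1.22 relative to all genes and above all 10000 random lists, and 6 more were detected in bone marrow alone. The unadjusted median of 1.05 was 0.24 with the normexp background. S100a8 (2.42 ± 0.15) and Ngp (2.0 ± 0.67) were highest. T cell markers had 2 of 14 higher and 3 lower, at 0.51, with Cd8b1 at 1.54 ± 0.13 and Cd2 at -5.08 ± 0.23, and their unadjusted median of 0.34 turned negative under 1 of 9 other settings. Another 4 T cell markers were detected in spleen alone and 0 in bone marrow alone, and with bounds the median over 18 genes was -0.19. Stromal and endothelial markers lay at 0.79 (1 of 7 higher, 0 lower), erythroid markers at 0.44 (1 of 6 higher, 1 lower) and basophil, mast cell and eosinophil markers at 0.39 (2 of 8 higher, 0 lower). Monocyte and macrophage markers lay at 0.19 (1 of 10 higher, 2 lower), with Cd68 at 1.11 ± 0.11 and the adaptor gene Tyrobp at -3.37 ± 0.18.

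The normexp background took 49 of 73 named genes of the comparison between organs from at least 2-fold to under it. Among them were Pecam1 (-0.65), Mcm3 (-0.63), Hmmr (-0.45), Id2 (-0.67), Egr2 (-0.74), Atm (-0.87), Cd86 (-0.84), Il23a (0.98), Fcer2a (0.87), S100a8 (0.94), Ngp (0.24), Cd8b1, Chst1, Ly6c1, Rfx5 and Cd68. The remaining settings did so for 16, among them Prdm1, Ero1a (-0.78) and Zbtb20 (-0.70), the last pair with scaling to the probes detected on all arrays.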

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

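The tests of explanations given below for granulocyte genes were chosen only after the result was seen, and the differences between the Venus+ populations were not tested. Egr1 is named by the fixed rule. The other 7 genes were chosen after their values were seen, because they moved in opposite directions against B220+ cells in the 2 organs.

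Against B220+ cells, 7 genes were higher in spleen and lower in bone marrow Venus+ cells, each at least 2-fold. Apoe, which encodes a lipid carrier made in quantity by macrophages, stood at log2 ratios of 2.37 and -2.32, with signals of 478 in B220+, 2472 in spleen Venus+ and 95.5 in bone marrow Venus+ cells. The immediate-early transcription factor gene Egr1 stood at 1.80 and -1.13. Plac8 stood at 1.13 and -2.73, Myo1e, an unconventional myosin gene, at 1.08 and -2.41, and the lipid transporter gene Abca3 at 1.72 and -1.43. Cyfip1 stood at 1.34 and -1.03 and the interferon-induced GTPase gene Gbp7 at 1.20 and -1.20. The reverse was seen for A930015D22Rik, at -1.33 in spleen and 1.66 in bone marrow. Of these 8 genes, 5 kept at least 2-fold in opposite directions when scaled to the probes detected on all arrays, where Egr1 stood at -0.84, Gbp7 at -0.91 and Cyfip1 at -0.74 in bone marrow. With quantile normalization 5 did, with cyclic loess 6, with probes above the 25th percentile 5, with the limit from spots without a probe 3 and with the normexp background 2. Apoe did so under each setting.

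The list of immediate-early genes had a median log2 ratio of 0.81 in spleen Venus+ and -0.33 in bone marrow Venus+ cells against B220+ cells, a difference that was not tested. Relative to all genes the bone marrow median was -0.09, above 5275 of 10000 random lists, so it lay near that of all genes.

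Spots printed without a probe, which entered no gene value and set only an alternative detection limit, carried signal above the detection limit from blank spots. Of 1102 such spots, 48.3% passed the limit on the B220+ array, 9.26% on the spleen Venus+ array and 26.6% on the bone marrow Venus+ array. Of blank spots, 7.97%, 7.97% and 8.19% passed it.

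Granulocyte genes were high in the B220+ array, although a B220 gate would remove granulocytes. The levels of S100a8 were 1649 in B220+, 12.5 in spleen Venus+ and 66.8 in bone marrow Venus+ cells, and those of S100a9 2552, not detected and 69.4. Of 15 detected granulocyte markers, none of which is in another list, 11 (73.3%) were at least 2-fold higher in B220+ than in spleen Venus+ cells, against 29.4% of macrophage, 50% of erythroid and 0% of T cell markers. This share restates the pattern, so granulocytes or their RNA in the B220+ sort cannot be told apart from a difference between the cells themselves. Under the other 3 scalings the list median in spleen Venus+ against B220+ cells stayed at -2.73 or lower. Those scalings moved the median of all genes there only from -0.02 to between -0.08 and 0.003. They could thus hardly have ended the pattern. Relative to all genes, which a single factor for the array leaves unchanged, the list median was -2.77. A single factor would not account for it.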

How the results depend on the processing

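The alternative with spots without a probe was chosen only after the result was seen, and the others were set beforehand. Of counts under alternatives, 54 were within 1.5 times and 26 moved further. Of list medians, 699 moved less than 1.5-fold, 47 moved further, some of them across 0, and 3 more changed sign from a reported median at least 1.5-fold away from 0. Of ratios of named genes, 3403 moved less than 1.5-fold, 306 moved further, some of them across 0, and 1 changed sign from a reported ratio of at least 2-fold. Many of the 3403 come from settings that could hardly move a ratio, so this total does not measure robustness. Scaling to shared probes and the limit from spots without a probe shift all ratios of a comparison alike, by under 1.5-fold. The percentile limit, no filter and the value table leave a measured ratio nearly as it was. With the normexp background, 235 moved further, 1 changed sign and 205 moved less. Cyclic loess moved 47 and left 364. The value table and the mean over probes moved no count past 1.5 times and no list median past 1.5-fold. Leaving out a replicate was not run, and no paired analysis was possible because each population has 1 array. Signal over background limits dim genes, whose ratios rest on signals near the blank spots. Below, medians are log2 ratios not taken relative to all genes, with the reported value first. The cause was not tested unless given.

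With a 4-fold threshold, which is stricter by construction, 588 genes were higher and 355 lower in spleen Venus+ against B220+, 964 and 1358 in bone marrow Venus+ against B220+, 57 and 250 in bone marrow against spleen Venus+, and 515 and 244 in both comparisons with B220+.

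With the normexp background, whose offset of 50 shrinks ratios of dim genes by construction, counts were 410 and 1174, 578 and 2142, and 62 and 315 in the same order, and 344 genes were higher in both. In spleen Venus+ against B220+, medians moved from 3.17 to 2.04 for the plasma cell programme, -1.22 to -0.60 for cell cycle, 1.76 to 0.49 for T cells, -2.79 to -1.51 for neutrophils, -1.37 to -0.54 for erythroid cells, 1.5 to 0.64 for basophils, mast cells and eosinophils and 1.02 to 0.26 for stroma. Prf1 went from -1.02 to 0.11. In bone marrow Venus+ against B220+, they moved from 3.46 to 2.38 for the plasma cell programme, -3.28 to -2.51 for mature B cells, 2.03 to 1.35 for ER folding, -0.93 to -0.31 for Il10-linked factors, -1.96 to -0.87 for cell cycle, -0.92 to -0.17 for chemokine receptors, 1.61 to 0.50 for T cells, -3.07 to -1.78 for neutrophils, 2.22 to 0.70 for basophils and related cells and 1.83 to 0.50 for stroma. In bone marrow against spleen Venus+, they moved from -1.55 to -0.93 for mature B cells, -1.17 to -0.41 for Il10-linked factors, -1.54 to -0.82 for immediate-early genes and 1.05 to 0.24 for neutrophils.

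With probes above the 25th percentile, where fewer genes are counted by construction, 986 genes were higher in spleen and 1346 in bone marrow Venus+ against B220+, 850 in both, and 287 higher and 1128 lower in bone marrow against spleen Venus+. Apoptosis regulators moved from 0.47 to -0.20 in spleen. Against B220+, bone marrow medians moved from -3.28 to -2.13 for mature B cells, -0.92 to -0.15 for chemokine receptors, -0.73 to -0.14 for interferon, -0.18 to 1.11 for macrophages and 0.01 to -2.17 for erythroid cells. Macrophages moved from 0.01 to 0.85 against spleen Venus+.

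With the limit from spots without a probe, 1047 genes were lower in spleen Venus+ against B220+ and 762 in both. There cell cycle moved from -1.22 to -0.61, interferon from -0.60 to 0.022 and erythroid cells from -1.37 to 0.40. In bone marrow against B220+, macrophages moved to 0.45 and erythroid cells to -0.69. With no filter, erythroid cells moved to 0.20 and basophils and related cells to 0.37 in spleen Venus+ against B220+, and in bone marrow platelets moved from -0.13 to 0.57, basophils and related cells to 0.81 and stroma to 0.81.

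With cyclic loess, medians in bone marrow Venus+ against B220+ moved to -2.57 for mature B cells, from 0.85 to 1.43 for secretion, to -0.25 for Il10-linked factors, from -0.78 to -0.19 for Toll-like receptors, from -0.38 to 0.23 for glycolysis, to -0.076 for interferon, -0.78 for macrophages, -1.95 for neutrophils and -1.07 for erythroid cells, and 1069 genes were lower in bone marrow against spleen Venus+. With quantile normalization, they moved to -0.14 for interferon, -2.02 for neutrophils and -0.95 for erythroid cells, and 916 genes were higher in bone marrow against spleen Venus+. Scaled to the probes detected on all arrays, 1250 genes were higher and 916 lower there.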

Other observations

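The tests of explanations given for B cell genes and T cell genes were chosen only after the result was seen, and the set of genes and of scalings in them was narrowed after first values.

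Interferon and nutrient genes showed the following in the spleen Venus+ against B220+ cells. The type I interferon response had 9 of 20 genes lower and 1 higher, with a median log2 ratio of -0.60, above 210 of 10000 random lists, and turned positive under 1 of 9 other settings. The antiviral genes Oas2 (-3.25 ± 0.57) and Oas1a (-2.68 ± 0.23) were lowest and Isg20 (2.97 ± 0.14) highest, the former at -0.50 and -0.91 with the normexp background. Amino acid transport and mTOR signalling had 6 of 21 higher and 2 lower, with a median of 0.23, led by the asparagine synthetase gene Asns (5.97 ± 0.37) and the amino acid transporter subunit gene Slc3a2 (4.17 ± 0.14). Apoptosis regulators had 2 of 17 higher, 2 lower and 13 between, with a median of 0.47 that turned negative under 1 of 9 other settings. The survival gene Bcl2 stood at 2.63 ± 0.15 and Birc3 at -1.67 ± 0.14. Toll-like receptor signalling had 2 of 20 higher and 4 lower, with a median of -0.08 that turned positive under 6 of 9 other settings, and with Ly96 at 2.03 ± 0.14 and Irak3 at -2.35 ± 0.16. Most housekeeping genes lay within 2-fold, with 33 of 36 genes of oxidative phosphorylation (median -0.10), 16 of 19 of glycolysis (0.15) and 37 of 40 cytosolic ribosomal protein genes (-0.27). Those 3 medians changed sign under 2, 2 and 1 of 9 other settings, and with 1 glycolysis gene detected in B220+ cells alone at its bound that median was -0.03.

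In bone marrow Venus+ against B220+ cells the same lists had medians of -0.48 relative to all genes for the interferon response (4 of 18 higher, 7 lower) and 0.55 for amino acid transport (8 of 19 higher, 4 lower), with Asns at 6.42 ± 0.37. Apoptosis regulators lay at 0.15 (2 of 16 higher, 4 lower), with Bcl2 at 3.18 ± 0.14, and Toll-like receptor signalling at -0.54 (1 of 18 higher, 9 lower), with Tlr1 at -2.82 ± 0.14. Oxidative phosphorylation lay at 0.05 (3 of 35 higher, 2 lower), glycolysis at -0.14 (2 of 18 higher, 4 lower) and ribosomal proteins at -0.22 (0 of 38 higher, 8 lower). The unadjusted medians of apoptosis, amino acid transport, oxidative phosphorylation and glycolysis changed sign under 4, 1, 4 and 2 of 9 other settings. In bone marrow against spleen Venus+ cells, Toll-like receptor signalling lay at -0.59 (0 of 18 higher, 5 lower, above 48 of 10000 random lists). There the interferon response lay at -0.29 (2 of 20 higher, 6 lower), apoptosis at -0.05 (1 of 17 higher, 1 lower), amino acid transport at -0.12 (0 of 20 higher, 4 lower) and oxidative phosphorylation at 0.24 (1 of 35 higher, 0 lower). Glycolysis lay at -0.10 (1 of 18 higher, 4 lower) and ribosomal proteins at -0.09 (0 of 38 higher, 1 lower). The unadjusted medians of apoptosis, amino acid transport, oxidative phosphorylation, glycolysis and ribosomal proteins changed sign under 1, 3, 2, 1 and 1 of 9 other settings.

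Markers of further cell types lay as follows, in spleen Venus+ against B220+, bone marrow Venus+ against B220+ and bone marrow against spleen Venus+ cells. Dendritic and plasmacytoid dendritic markers had 5 of 11, 4 of 10 and 1 of 10 genes higher and 2, 1 and 2 lower, with Cox6a2 at 3.69 ± 0.27 and Siglech at -1.70 ± 0.17 in the first. Their medians were 0.48, then 0.52 and 0.10 relative to all genes, and the unadjusted ones changed sign under 1 of 9, 0 of 8 and 5 of 9 other settings. In the second, 2 more were detected in B220+ cells alone, and with bounds the unadjusted median over 12 genes was -0.16 in place of 0.28. Megakaryocyte and platelet markers had 0 of 7, 0 of 6 and 0 of 6 higher and 1, 1 and 0 lower, with medians of -0.03, then 0.12 and 0.12 relative to all genes, the unadjusted ones changing sign under 2 of 7, 3 of 7 and 5 of 8. In the first comparison immature B cell markers (1 of 5 higher, 0 lower) had a median of 0.14 and NK cell markers (2 of 6 higher, 1 lower) one of 0.41. In the others under 5 members were detected on both arrays. Flt3 and Ctla2a stood at 1.88 and 0.73 in bone marrow Venus+ against B220+ cells, and at -0.17 and 0.38 against spleen Venus+ cells, where Kit stood at -0.01. Gzma, Eomes, Klrd1 and Ccl5 stood at 1.36, 1.43, 0.58 and 0.34 against B220+ cells and at 0.24, 0.67, 0.80 and -1.05 against spleen Venus+ cells.

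Sensory receptor genes, chosen after the data were seen and numbering 771 on the array, had 61 higher and 9 lower of 297 detected on both arrays in spleen Venus+ against B220+ cells, 92 and 14 of 254 in bone marrow Venus+ against B220+ cells and 25 and 6 of 296 in bone marrow against spleen Venus+ cells. Their medians were 0.40, 0.69 and 0.23. In spleen 20.5% were higher and 3.03% lower, against 15.7% and 16.5% of all genes. In bone marrow Venus+ against B220+ cells 36.2% were higher and 5.51% lower, against 22.4% and 30.7% of all genes. Between the organs 8.45% were higher and 2.03% lower, against 4.33% and 15.2%. With the normexp background 9, 16 and 2 were higher. Signals of at least 25 were reached by 30 sensory receptor genes in B220+, 50 in spleen Venus+ and 65 in bone marrow Venus+ cells. Higher calls among dim genes of other lists may carry a like excess, which was not tested.

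In spleen Venus+ cells, 23 of 31 genes of mature B cell identity and 4 of 8 of MHC class II presentation lay between a higher level in B220+ and a lower level in bone marrow Venus+ cells. Carried-over B220+ cells without CD138, which a CD138 gate would remove, would bring all these genes at about 1 share. The labels give no gate against B220 for the Venus+ sorts, so B220+ cells that also carry CD138 are not covered by this test. Among 22 genes of the mature B cell and MHC class II lists with a B220+ signal of at least 100 and a level at least 4-fold lower in bone marrow Venus+ cells, the bone marrow level was subtracted from the spleen Venus+ and the B220+ level, with undetected levels set to 0, and the first difference taken as a share of the second. This share had a 90th percentile 11.7 times its 10th (52.6% and 4.50%), from 0% for Cr2 to 139% for Blk. It argues against carry-over of cells without CD138 as the whole cause. Under the other 3 scalings the median of mature B cell identity in bone marrow against spleen Venus+ cells stayed at -1.22 or lower. Those scalings moved the median of all genes there from -0.17 to at most 0.16, so they could hardly have ended the pattern. Relative to all genes, which a single factor for the array leaves unchanged, the list median was -1.38. A single factor would not account for it. Some carry-over stays open, as does a less advanced stage of plasma cell differentiation in the spleen, which may fit the design's difference in organ and was not tested.

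T cell genes were high in the Venus+ arrays, with signals of Cd247 at 15.7 in B220+, 637 in spleen Venus+ and 1038 in bone marrow Venus+ cells, and of Cd3g not detected, 55.7 and 8.95. T cells of a single kind, which a CD138 gate would remove, would keep their genes in 1 ratio between the Venus+ arrays. The test took 7 markers at least 2-fold higher in spleen Venus+ than in B220+ cells, with a signal of at least 25 on a Venus+ array. Their log2 ratios of bone marrow over spleen spanned 4.96, from Cd5 (-3.43) and Cd3g (-2.64) to Cd8b1 (1.54), with a spot error of 0.28. That argues against such cells as the whole cause. The span was 1.89 with the normexp background, which shrinks ratios by construction, with Cd5 at -1.28 and Cd247 at 0.50. That is short of the 2 set as the limit of this test. With probes above the 25th percentile, Cd5 and Cd3g dropped out and the remaining 5 markers spanned 2.22, little over that limit. The argument is weaker under both settings. Different T cells in the 2 organs, and plasma cells that express some of these genes themselves, stay open as untested. Of the T cell list 1 gene is in another list, and Cd2, Cd5 and Cd27 are also known from B lineage cells. Under the other 3 scalings the median of the T cell list against B220+ cells in spleen stayed at 1.36 or higher. Those scalings moved the median of all genes there only from -0.02 to between -0.08 and 0.003, so they could hardly have ended the pattern. Relative to all genes, which a single factor for the array leaves unchanged, the list median was 1.78. A single factor would not account for it. The normexp background took the unadjusted median to 0.49, so part of it may lie in dim signals.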
